A study of Mus musculus with 2 samples.

How the data were processed

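Messenger RNA was measured by sequencing on an Illumina HiSeq instrument in 2 libraries of sorted ileal epithelial cells from wildtype mice, both of 1 group. Per the submitters' processing notes, TopHat2 2.0.14, Cufflinks 2.2.1 and the mm10 assembly were used. The gene annotation, the read length, the strand setting and the treatment of reads with several matches are not given in the sources used here. The values deposited by the authors are FPKM, fragment numbers scaled to transcript length and to the mapped fragments of the library, with 1 value per gene symbol in each library. FPKM are not counts, so no count model was used. A read that matches several near-identical genes can be divided among them or lost, which bears on the NAIP and alpha-defensin genes.

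The deposited tables held 24384 rows, and 27 of them carried a calendar date in place of a gene symbol, as spreadsheet programs make of some names, and were left out, leaving 24357. Depth was read from the lowest FPKM values, where a gene holds 1 fragment: FPKM times the transcript length less 160 bases gave the worth of 1 fragment, and from it about 16200000 and 26100000 fragments. The commonest ratio of low values between the libraries gave 1.63 for the same quantity. Of low values, 62.6% in replicate 1 and 62.7% in replicate 2 lay within 0.05 of a whole number of fragments, so that whole counts were not recovered for all genes and depths are approximate. No housekeeping or epithelial identity gene was listed at 0, while 1 of 83 ribosomal protein symbols was, so a value of 0 is reported only as listed at 0.

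Values were used as log2(FPKM + 1), a scale that understates differences of low genes. A gene counted as expressed at 1 FPKM or more in both libraries. The place of the NLRs was taken as the median of their percentiles among all genes and set beside 10000 random lists of the same size; it was 42.0, with 32.8 to 66.5 as the central 95% of random lists. NLR genes next to each other in level were called separated where both libraries gave the same order without overlap and the difference of means exceeded the 95th percentile of the absolute difference between libraries among the 200 genes nearest in level. Lists of sensor genes were compared by an exact two-sided permutation test of the rank sum with midranks for ties, with Benjamini-Hochberg adjustment over 5 comparisons and a threshold of 0.05. These p values compare genes by their mean level over the 2 libraries. The spread behind them is that among genes, and differences between the libraries do not enter.

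For differences between the libraries, the median of replicate 2 minus replicate 1 over list members with a mean of at least 1 FPKM was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. Gene lists, tests, thresholds and the rule for named genes were fixed before the data were examined, apart from the tests and alternatives named in the text as chosen after the result or the data were seen. The rule takes every NLR with a mean of at least 1 FPKM, the 3 highest members of each other list, the 3 members with the largest difference of each list outside the central 95%, the 15 highest genes, and the 10 genes each way with the largest difference between libraries among those with a mean of at least 5 FPKM. Genes named outside it, such as Nod2, Ciita, Nlrc5, Nlrp3, Nlrp9a, Nlrp9c, Epcam, Gp2, Lars2 and Rn45s, were chosen after their values were seen.

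Coordinates, transcript lengths and GC content came from GENCODE release M21, which is built on the same assembly. Length and GC content were matched for 96.5% of the 10601 genes with a mean of at least 1 FPKM, and the trend was removed as the median difference in cells of similar length and GC content. The overall median difference of 0.11 was then added back, so values with the trend removed lie around 0.11 and not around 0. For red blood cell and pancreas transcripts the removal of the trend is void as a check, since only 3 of 4 members had a length. Shared sequence was measured as the percent of a gene's 50-base words that occur in transcripts of other genes. The tests were tried on simulated data, where the exact test equalled full enumeration in 20 of 20 draws. For the list comparison, differences were shuffled among genes of similar level and random lists of a fixed size were drawn. It called 5 of 100 lists with no shift, 72 of 100 with a shift of 0.25 and 100 of 100 with a shift of 0.5. Genes that vary together were not simulated, so these rates do not carry over to lists of related genes. Alternatives changed the pseudocount, the minimum FPKM, the scaling, the statistic and the libraries used. Computations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.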

Results

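The series measured messenger RNA in epithelial cells of the ileum, the last part of the small intestine, from wildtype C57BL/6 mice, and its title names the NOD-like receptors (NLRs) as the target of the measurement. NLRs are cytosolic proteins that sense microbial products and cell damage, and several of them assemble inflammasomes, the complexes that activate caspase-1. Epithelial cells were released with EDTA and sorted as live cells positive for the epithelial surface protein EpCAM and negative for the leukocyte protein CD45. There was 1 group of 2 libraries, called replicate 1 and replicate 2 here in accession order, so no contrast between treatments exists. Nothing in the labels says that the 2 samples came from separate animals or cultures, so the spread given here is that between these samples. The libraries differed in sex-linked transcripts: Xist, the RNA of the inactive X chromosome, had 7.91 FPKM in replicate 1 and 0.00640 FPKM in replicate 2, and the Y-linked gene Eif2s3y had 0 and 14.9 FPKM, so replicate 1 carried female and replicate 2 male transcripts and they did not come from the same animal. Values are FPKM per gene symbol, and every ± is the SD over the 2 libraries (n = 2). Values of 24357 named genes were used, of which 10293 reached 1 FPKM in both libraries. The steps between the lowest values implied about 16200000 fragments for replicate 1 and 26100000 for replicate 2, a ratio of 1.61.

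Which NLRs the epithelium expressed was the question of the series. Nlrp6, an inflammasome-forming receptor of the intestinal epithelium, was the highest at 50.8 ± 1.12 FPKM, followed by Naip5, a receptor for bacterial flagellin, at 45.6 ± 9.14 FPKM. Nlrp9b, a receptor linked to the sensing of rotavirus RNA, stood at 30.7 ± 10.1 FPKM. Naip1 at 20.6 ± 1.63 FPKM, Naip2 at 19.1 ± 0.418 FPKM and Naip6 at 15.9 ± 0.543 FPKM were also expressed. These NAIPs bind flagellin or parts of the bacterial type III secretion system. Naip7 was listed at 8.22 ± 1.93 FPKM, but had no entry in the annotation used for coordinates. Nlrc4, the partner with which NAIPs form an inflammasome, reached 12.8 ± 1.85 FPKM.

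Of 33 NLR symbols fixed in advance 32 were listed, and 10 of them reached 1 FPKM in both libraries. Below the 8 genes above stood Nlrx1, a mitochondrial NLR, at 2.81 ± 1.87 FPKM, and Nlrp1b at 2.13 ± 0.545 FPKM. Nod1, a receptor for bacterial peptidoglycan fragments, had 1.62 FPKM in replicate 1 and 0.913 FPKM in replicate 2. The 8 highest NLRs held 96.2% of the summed NLR FPKM in replicate 1 and 97.0% in replicate 2. The NAIPs alone held 52.3% and 51.4%. NAIP levels carry a further uncertainty, because a median of 26.5% of the 50-base words of Naip1, Naip2, Naip5 and Naip6 occur in other genes as well. Naip7, counted among the 10 genes and in the NAIP share, could not be examined in this way.

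The other members were low. Nod2, the second peptidoglycan receptor, had 0.0695 FPKM in replicate 1 and 0.0765 FPKM in replicate 2, and Ciita, the activator of MHC class II genes, had 0.285 and 0.238 FPKM. Nlrc5, the activator of MHC class I genes, had 0.229 and 0.112 FPKM. Nlrp3, the inflammasome receptor best known from myeloid cells, was listed at 0 in both libraries, against a level of 0.0480 FPKM in replicate 1 and 0.0297 FPKM in replicate 2 that 3 fragments would give. In all, 12 NLRs were listed at 0 in both libraries and 18 stayed under 0.1 FPKM in both. Within the NLRP9 group the signal sat in Nlrp9b, with Nlrp9a at 0.0432 and 0.0818 FPKM and Nlrp9c at 0 and 0.0531 FPKM. Such floors cover counting error only and rest on the depth read from the values.

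**Figure D1:**
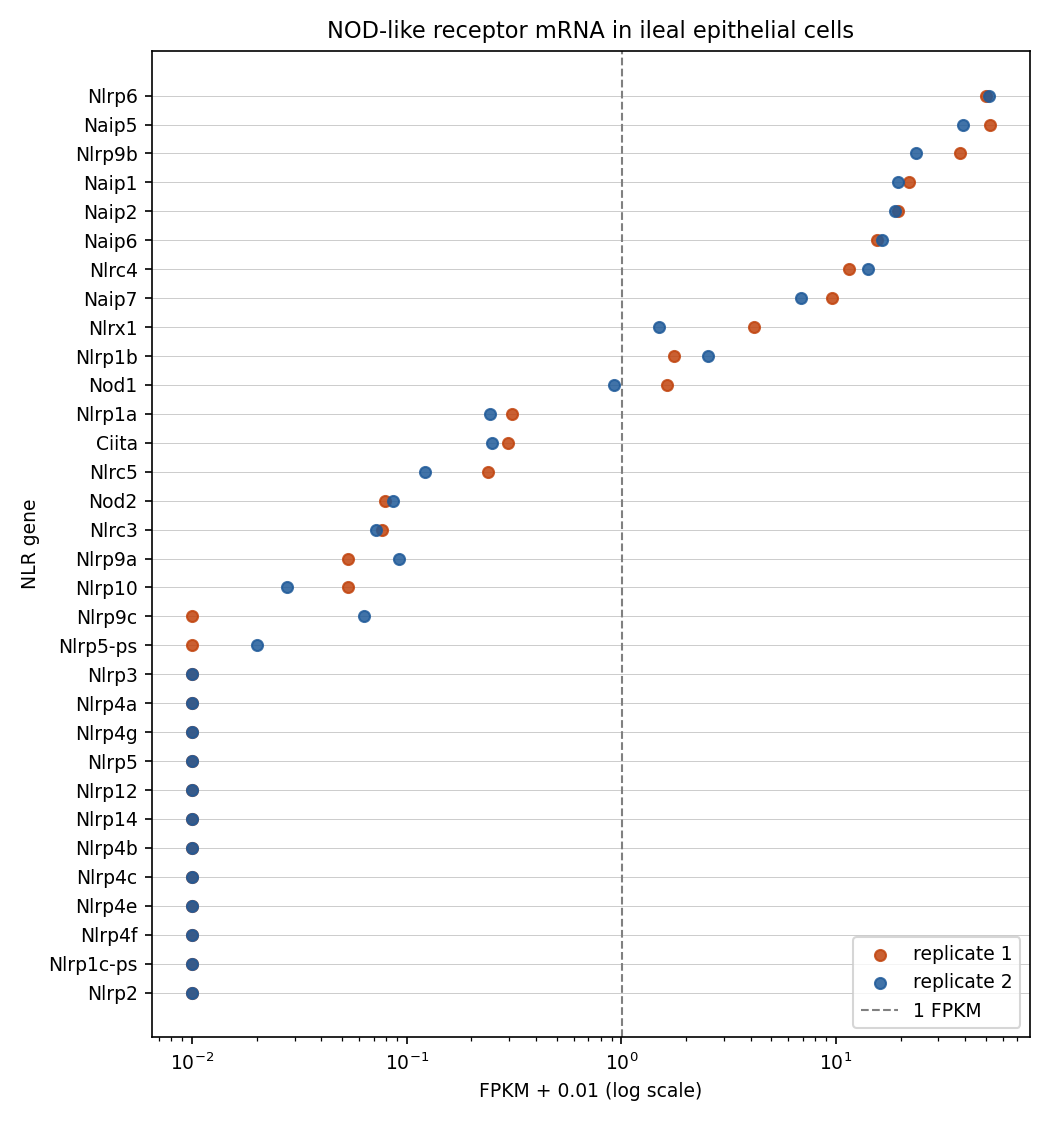
Each row is an NLR gene and each point is its FPKM in replicate 1 or replicate 2, plotted as FPKM + 0.01 on a log axis with a dashed line at 1 FPKM. Nlrp6, with a mean of 50.8 FPKM, and Naip5, with one of 45.6 FPKM, lie at the top, and 12 genes lie at 0 in both libraries.

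In the mm10 assembly, Nlrp6 lies on chromosome 7 from 140920902 to 140929192 on the plus strand, and Nlrp9b lies on the same chromosome from 19991465 to 20073306. The listed NAIPs with coordinates form a cluster on the minus strand of chromosome 13, with Naip2 from 100144063 to 100202092, Naip5 from 100211739 to 100246323, Naip6 from 100281121 to 100317674 and Naip1 from 100407764 to 100452869. Nlrc4 lies on chromosome 17 from 74425438 to 74459142. All of these are annotated as protein-coding genes, and FPKM here summarises their exons. Naip7 had no entry in the annotation used for coordinates. With the depth above, Nlrp6 would rest on about 3461 and 5765 fragments, Naip5 on about 4252 and 5160, and Nlrp9b on about 1951 and 1960.

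The order of these genes exceeded the spread between the libraries only across larger steps. Naip5 exceeded Nlrp9b by 0.58 on the log2(FPKM + 1) scale, more than the 0.51 that marks the 95th percentile of the difference between libraries for genes of that level. Nlrp9b itself differed by -0.66 between the libraries, larger in size than both values, so this step is weak. Naip7 exceeded Nlrx1 by 1.35, against a limit of 0.65. These limits do not cover how reads shared among the NAIPs were divided. Nlrp6 and Naip5 differed by 0.17, less than the limit of 0.59, and their values overlapped, so they were not separated. Over the 11 NLRs with a mean of at least 1 FPKM, 2 of 10 neighbouring pairs and 44 of all 55 pairs were separated. With 2 values per gene an exact two-sided permutation test cannot go below p = 0.333, so no p is given for single genes.

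By median, partners and targets of the inflammasome lay above the NLR list, in which 12 of 32 members were listed at 0 in both libraries. Gsdmd, which forms the pore of pyroptosis, reached 242 ± 21.8 FPKM, Pycard, the adaptor ASC, 106 ± 3.59 FPKM, and Gsdmc4, another gasdermin, 90.5 ± 4.21 FPKM. Of 19 genes in this list 12 reached 1 FPKM in both libraries. All NLRs together had a median 4.41 below this list on the log2(FPKM + 1) scale, a difference of -4.41 (exact two-sided permutation test of the rank sum over 32 and 19 genes, p = 0.000521, Benjamini-Hochberg adjusted p = 0.00130). With genes under 0.1 FPKM left out it was -1.31 (exact adjusted p = 0.175), and with genes under 1 FPKM left out -1.26 (exact adjusted p = 0.0644), so the call was lost. Within the family, the 20 NLRP genes lay below the 12 other NLRs, with a difference of medians of -2.51 (exact p = 0.000207, adjusted p = 0.00104). The NLRP list includes the annotated pseudogenes Nlrp1c-ps, Nlrp4g and Nlrp5-ps. Without pseudogenes and Naip7 the difference was -1.84 (exact adjusted p = 0.00380). The call within the family was lost and the ranks turned with genes under 0.1 FPKM (-0.19, exact adjusted p = 0.645) or 1 FPKM (1.02, exact adjusted p = 0.863) left out. The size of both differences depended on the pseudocount, the NLRP median being 0 FPKM and the NLR median 0.0635 FPKM: with 0.1 and 0.01 in place of 1 they were -5.53 and -8.81 within the family and -7.05 and -8.22 against the inflammasome list.

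RIG-I-like and cytosolic nucleic acid sensors were led by Zbp1, a sensor of Z-form nucleic acid, at 51.9 ± 28.9 FPKM, Oas1a, an activator of RNase L, at 47.1 ± 22.3 FPKM and Oasl2 at 40.8 ± 15.5 FPKM, and 10 of 16 reached 1 FPKM in both libraries. Among 12 Toll-like receptors only Tlr3, the receptor for double-stranded RNA, did so, at 4.07 ± 0.260 FPKM. Of 15 C-type lectin receptors, Clec2d with 117 ± 11.2 FPKM and Ly75 with 5.38 ± 0.0288 FPKM passed the same minimum. NLRs lay below the nucleic acid sensors by a difference of medians of -2.77 (exact p = 0.0154, adjusted p = 0.0257), or -5.28 and -6.43 with the smaller pseudocounts. That call was lost without replicate 1, with a difference of -2.41 and an exact adjusted p = 0.0855. Against Toll-like receptors the difference was 0.00457 (exact p = 0.781, adjusted p = 0.781) and against C-type lectin receptors 0.0806 (exact p = 0.275, adjusted p = 0.344). These 5 comparisons run across genes, which are not independent replicates, and none of the 3 calls held when genes under 0.1 FPKM were left out.

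**Figure D2:**
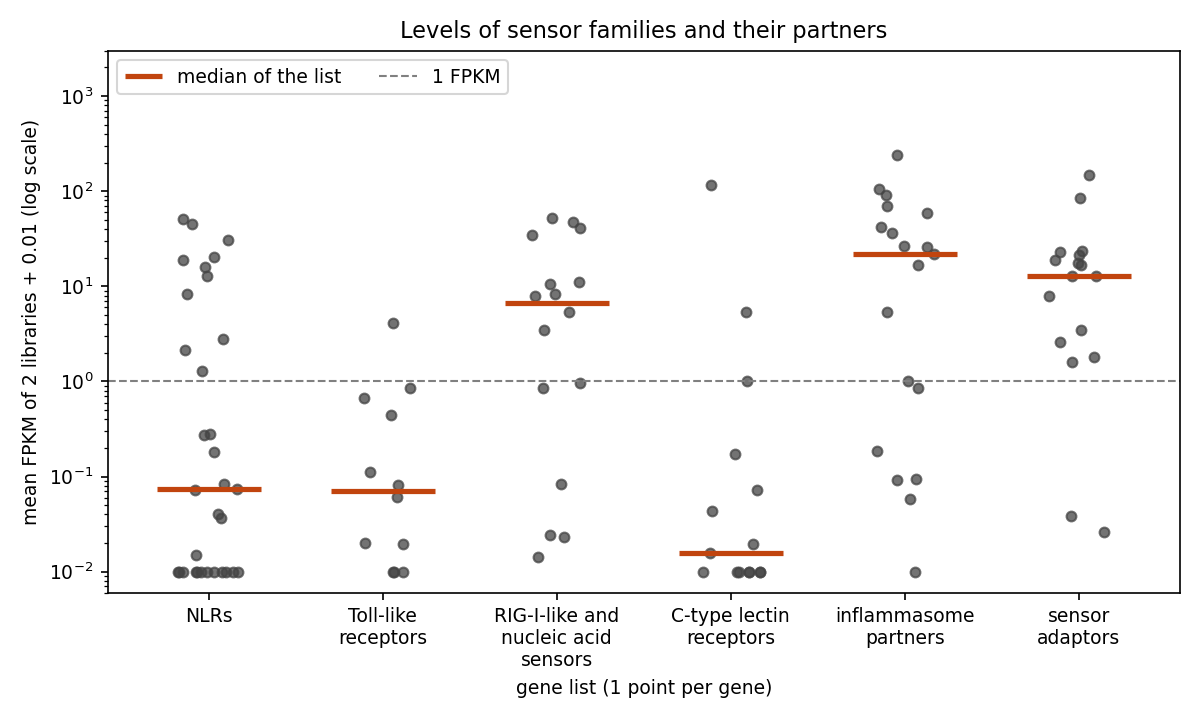
Each point is a gene at its mean FPKM over the 2 libraries + 0.01 on a log axis, grouped by gene list, with the median of each list as a bar and a dashed line at 1 FPKM. The inflammasome list has a median of 21.7 FPKM and the NLR list one of 0.0635 FPKM.

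Most genes of the partner, adaptor and cytokine receptor lists reached the minimum, at widely different levels. Of 22 partners of NOD signalling and autophagy, 19 reached 1 FPKM in both libraries, led by Slc15a1, the peptide transporter PEPT1, at 118 ± 5.46 FPKM. The lowest of these 19, Ripk2, had 1.38 and 1.66 FPKM. Among 17 sensor adaptors and transcription factors 15 did, led by Irf7 at 150 ± 71.7 FPKM and Irf1 at 86.0 ± 1.23 FPKM, both transcription factors of interferon responses. Receptors for interferons and related cytokines included Ifngr2, part of the interferon gamma receptor, with 92.7 and 108 FPKM and Il10rb, a subunit shared by the receptors for interferon lambda and IL-10, at 57.4 ± 7.02 FPKM.

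Transcripts of absorptive and secretory epithelial lineages were abundant in the sorted cells. Epithelial identity genes reached 1 FPKM in both libraries in 16 of 16 cases, with Krt8 at 2249 ± 301 FPKM and Epcam, the protein used for the sort, at 670 ± 36.8 FPKM. Absorptive enterocyte genes had a median of 406 FPKM, led by the apolipoprotein gene Apoa1 at 16969 ± 3315 FPKM. Paneth cell genes had a median of 955 FPKM and goblet cell genes one of 262 FPKM. Enteroendocrine genes had a median of 178 FPKM, led by Gip, the incretin hormone gene, at 1194 ± 70.7 FPKM. Proliferation genes stood at 13.1 FPKM, stem and crypt base genes at 5.60 FPKM, M cell and follicle-associated genes at 5.52 FPKM and tuft cell genes at 3.34 FPKM. The M cell list was led by Marcksl1 at 26.3 ± 8.75 FPKM, while Gp2, a surface receptor of mature M cells, had 0.374 and 0 FPKM. The housekeeping list had a median of 230 FPKM.

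Markers of cells outside the epithelium were near the floor. The median was 0.339 FPKM for T cell and intraepithelial lymphocyte genes, 0.0764 FPKM for myeloid genes, 0.0411 FPKM for B and plasma cell genes, 0.0430 FPKM for fibroblast genes, 0.0634 FPKM for endothelial genes, 0.0203 FPKM for smooth muscle genes and 0.0832 FPKM for neuron and glia genes. Transcripts of red blood cells and pancreas had a median of 0.00176 FPKM, with Hbb-b1, a globin gene, the highest at 24.4 ± 2.84 FPKM. Hba-a1, another globin gene, had 17.2 ± 2.23 FPKM. Outside the globins, exceptions with a mean above 10 FPKM were Xbp1 at 80.2 ± 2.39 FPKM in the plasma cell list and Mylk at 17.2 ± 2.05 FPKM in the smooth muscle list, and both genes are also known from epithelial cells.

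**Figure D3:**
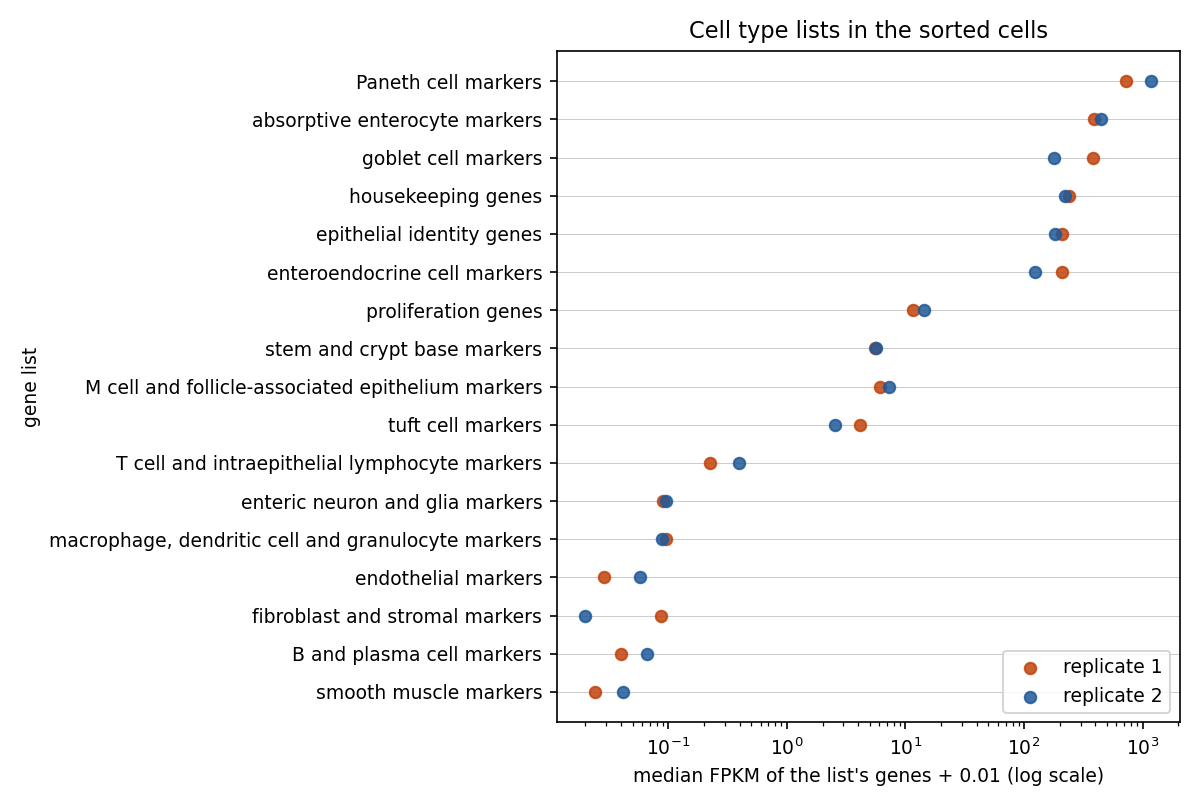
Each row is a gene list and each point is the median FPKM of its genes in replicate 1 or replicate 2, plotted as FPKM + 0.01 on a log axis. Paneth genes (729 and 1186 FPKM) are in the top row and smooth muscle genes (0.0141 and 0.0318 FPKM) in the bottom row of the lists drawn, which are ordered by the median of their genes' mean FPKM.

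Between the libraries, Paneth and goblet cell genes differed in opposite directions, and the enteroendocrine and tuft lists, given below, were lower like goblet genes. Paneth cell genes were higher in replicate 2 in 16 of 18 cases, with a median difference of 0.83 in log2(FPKM + 1), or 0.43 over the 10 members that are not alpha-defensins, and the alpha-defensin gene Defa24 went from 9295 FPKM in replicate 1 to 17390 FPKM in replicate 2. Goblet cell genes were lower in replicate 2 in 14 of 15 cases, with a median of -0.66, and Muc2, the gel-forming mucin, had 381 and 142 FPKM. Proliferation genes were higher in replicate 2 in 18 of 18 cases (median 0.43), with Pcna at 78.1 and 111 FPKM. Stem and crypt base genes had a median of 0.33, with Olfm4 at 259 and 466 FPKM. Each of these 4 medians lay outside the central 95% of 10000 random gene lists matched on expression, which describes these 2 libraries and is not a p.

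Several lists of immune genes were lower in replicate 2. Nucleic acid sensors were lower in 10 of 10 cases (median -0.76, or -0.21 and still outside the central 95% with no minimum FPKM) and interferon-stimulated genes in 17 of 18 (median -0.41), with Isg15, a ubiquitin-like interferon-induced protein, at 144 and 73.5 FPKM. MHC class I genes had a median of -0.42 with 9 lower and 3 higher, and one of -0.20 with the GC and length trend removed. The transporter gene Tap1 had 35.3 and 18.3 FPKM, while B2m, the highest member, had 2006 and 2113 FPKM. MHC class II genes had a median of -0.58, with Cd74, the invariant chain, at 24.5 and 12.5 FPKM. Antimicrobial genes had a median of -0.69 with 9 lower and 5 higher, or -0.29 and still outside with no minimum FPKM, and Reg3b, a C-type lectin active against bacteria, had 22213 and 8616 FPKM. Retnlb, a member of both the antimicrobial and the goblet list, had 35.4 and 5.78 FPKM. Tuft cell genes had a median of -0.56 and enteroendocrine genes one of -0.25, with Pyy, a gut hormone gene, at 260 and 96.3 FPKM. Ileal and bile acid genes had a median of -0.25, with Fabp6, the ileal bile acid binding protein, at 1247 and 390 FPKM.

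The NLR median lay nearer to 0. The 11 members with a mean of at least 1 FPKM had a median difference of -0.15, at percentile 1.83 of random lists. By subgroup the medians were -0.15 for the NAIPs (percentile 7.79), -0.45 for Nod1, Nlrc4 and Nlrx1 (percentile 1.45, but -0.08 and inside with no minimum FPKM) and 0.04 for the NLRP genes (percentile 40.1). With the GC and length trend removed they were -0.16 over 4 of 5 NAIPs (percentile 2.28), -0.08 (percentile 13.1) and 0.22 (percentile 79.3), and that of all NLRs was -0.08 over 10 of 11 members (percentile 1.42), which had -0.10 (percentile 5.25) before the removal. Nlrx1 had 4.13 and 1.49 FPKM and Nlrp9b 37.8 and 23.5 FPKM, while Nlrp6 differed by 0.04 on the log2 scale, or 0.26 with the trend removed. The median over all genes was 0.11 in both cases, so Nlrp6 lay below it before the removal and above it after. With genes under 5 FPKM left out, the family median was -0.10 and lay inside the central 95%. With no minimum it was 0, but 12 of 32 members were listed at 0 in both libraries. Genes near 0 FPKM cannot differ much in log2(FPKM + 1), so medians with no minimum decide little for lists with many of them.

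Over 10601 genes with a mean of at least 1 FPKM the libraries correlated with Pearson's r = 0.980 and Spearman's rho = 0.973, across genes, which are not independent replicates. The median difference was 0.11, the 95th percentile of the absolute difference was 0.65, and 60 genes were higher and 102 lower in replicate 2 by more than 1 on the log2 scale. With replicate 2 rescaled by the median ratio the split was 46 higher and 134 lower. Of 33 lists with 3 or more members, 22 lay outside the central 95% of random lists, 6 higher and 16 lower. The sex-linked list is among them. For lists of unrelated genes 1.65 would be expected, but members of a list can vary together, so the 2 numbers make no test. The difference between libraries went with the GC content of the gene (Spearman's rho = -0.503 over 10227 genes), from a median of 0.28 in the fifth of genes with the lowest GC content to -0.15 in that with the highest. With the trend on GC content and length removed, an alternative chosen after seeing the data, 20 lists lay outside, 18 of them outside before as well. Absorptive enterocyte genes (0.19 before, 0.12 after) and epithelial identity genes (-0.14 and -0.04) no longer did, while inflammasome partners (0.04 and -0.09) and the 4 of 5 NAIPs with a length (-0.10 and -0.16) newly did.

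**Figure D4:**
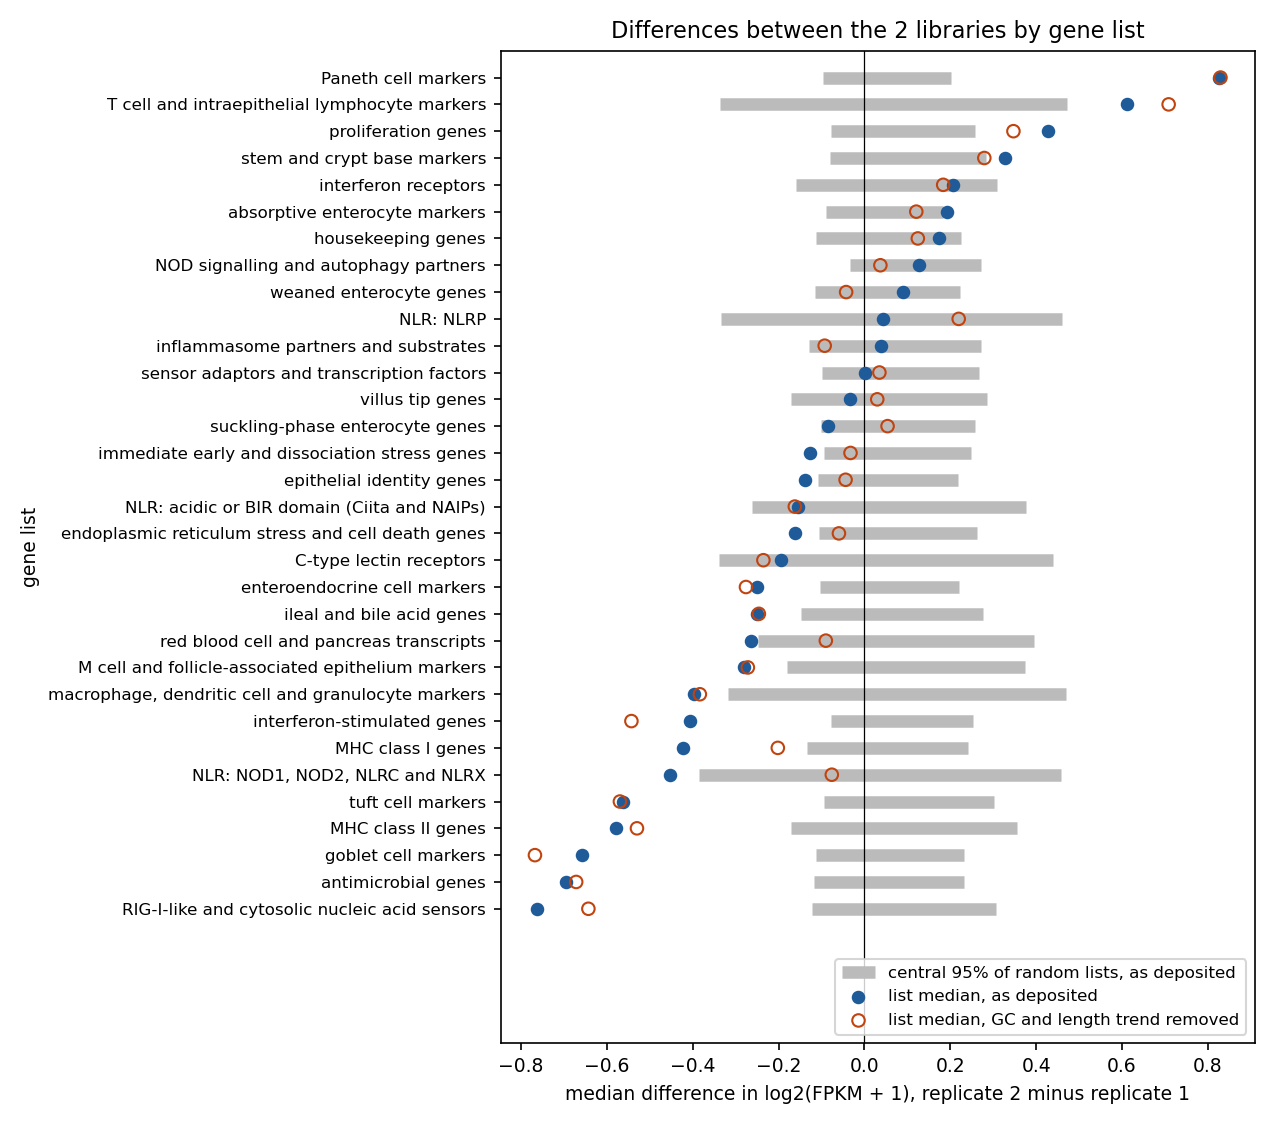
Each row is a gene list, the filled point is the median of its genes' difference in log2(FPKM + 1) between the libraries (replicate 2 minus replicate 1), the open point is the same with the GC and length trend removed, and the grey bar is the central 95% of matched random lists for the deposited values; the sex-linked list is not drawn. Paneth genes (0.83) lie to the right and goblet genes (-0.66) to the left of the bars.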

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

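Signal also appeared in rows that no comparison used. Of the 27 rows named by a date, 15 reached 1 FPKM in both libraries, and the highest had a mean of 179 FPKM. Together these rows held 0.106% of the summed FPKM in replicate 1 and 0.101% in replicate 2. Such names arise when spreadsheet programs rewrite symbols that look like months, and the rows were not assigned to genes.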

How the results depend on the processing

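Of 288 alternatives to 46 results, 256 left a result on its side of the threshold or of the central 95%, or a value or count within a tolerance (1.5 times for counts, so that 2 calls in place of 3 pass); its size could still change, as with nucleic acid sensors (-0.76 and -0.21 with no minimum). Those for pseudogenes, alpha-defensins, a minimum of 1 FPKM and the GC trend were chosen after seeing the data. Among the sensor comparisons, a minimum changed the most calls, while a smaller pseudocount kept the calls and changed the sizes. With genes under 0.1 FPKM left out, the NLR median percentile rose from 42.0 to 64.9, and the number of sensor comparisons past the threshold went from 3 to 0, as it did with a minimum of 1 FPKM (0). NLRP against other NLRs then gave -0.19 (exact adjusted p = 0.645) and 1.02 (0.863), and the ranks turned to the other direction in both. NLRs against nucleic acid sensors gave 0.11 and 0.52, and against inflammasome partners -1.31 and -1.26. By construction these minima remove most of one side, since 16 of 20 NLRP genes lay under 0.1 FPKM in both libraries.

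Against nucleic acid sensors the call was also lost with the difference of means (-1.29, permutation adjusted p = 0.0680) and without pseudogenes and Naip7 (-2.76, exact adjusted p = 0.0537). Leaving out either library gave -2.98 to -2.41, and the call was lost without replicate 1. Over all alternatives of that comparison the adjusted p ran from 0.0204 to 0.863. The correlation of libraries was 0.969 with a pseudocount of 0.1 and 0.992 with no minimum. Genes differing by more than 1 log2 numbered 267 with a pseudocount of 0.1 and 102 with a minimum of 5 FPKM, against 162. The NLR list difference was -0.10 with a minimum of 5 FPKM and 0 with none, where 12 of 32 members were listed at 0 in both libraries. The absorptive list fell to 0.12 with the GC trend removed. The causes of these changes were not tested. Depth limits statements on NLRs listed at 0 to what 3 fragments would give, from 0.0170 to 0.0991 FPKM by gene and library.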

Other observations

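Genes that change around weaning were read as 2 lists; the sample titles hold codes that the labels do not explain, so no age was assigned. Sucrase-isomaltase (Sis) had 276 and 284 FPKM in the libraries, and the list of genes higher after weaning had a median of 241 FPKM. Lactase (Lct), known to be higher before weaning, had 267 and 349 FPKM, and 14 of 17 genes of its list reached 1 FPKM in both libraries. The median differences between libraries were 0.09 and -0.09, both inside the central 95% of random lists, but the second was -0.24 and outside (percentile 2.15) with replicate 2 rescaled by the median ratio. The first median hides opposite moves. Of the 14 genes higher after weaning, 3 were higher and 5 lower in replicate 2 by more than 0.5, from Fut2 (-1.98) to Defa24 (0.90). Genes of the villus tip had a median of 74.0 FPKM and a difference of -0.03. Immediate early and dissociation genes were high, with Fos at 138 ± 7.46 FPKM and a list median of 41.0 FPKM. They were lower in replicate 2 by a median of -0.13, or -0.03 with the GC and length trend removed. Both medians lay outside the central 95%, the second at percentile 1.755. Genes of endoplasmic reticulum stress and cell death, led by the chaperone Hspa5 at 156 ± 28.9 FPKM, had a median difference of -0.16. It was -0.06 and still outside the central 95% (percentile 1.78) with the GC and length trend removed. With a minimum of 5 FPKM it was -0.11 and inside.

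Several single genes differed strongly between the libraries. Plb1, an intestinal phospholipase, had 170 and 20.5 FPKM. The near-identical genes Eif3j1 and Eif3j2 went opposite ways, with 0.0896 and 15.1 FPKM for the first and 11.1 and 0.912 FPKM for Eif3j2. Small RNAs such as Snord16a, with 96.0 and 0 FPKM, and Mir5131, with 0 and 99.3 FPKM, were among the extremes. Rn45s, a ribosomal RNA precursor, had 1821 and 831 FPKM, and Lars2 had 377 and 129 FPKM. The Y-linked gene Ddx3y had 0.0138 and 4.71 FPKM. The list of 5 sex-linked genes had a median difference of 2.11. Among lists of other cells, the lymphocyte list had 0.61 over 3 genes, with Gzma at 2.72 and 7.29 FPKM, Cd7 at 0.766 and 1.70 FPKM and Ccl5 at 12.9 and 5.69 FPKM, and 0.05, inside the central 95%, with no minimum FPKM. The myeloid list had -0.40 over 3 genes, and -0.28, inside the central 95%, rescaled to TPM. Red blood cell and pancreas transcripts had -0.26, but lay inside with a pseudocount of 0.1 (-0.30), rescaled to TPM (-0.31) and with no minimum (0, percentile 48.5). M cell genes had -0.28, with 3 higher and 4 lower and the largest difference in Ccl20, a chemokine gene higher in replicate 2 (1.52 and 7.95 FPKM). Lists inside the central 95% were C-type lectin receptors (-0.19), inflammasome partners (0.04, but -0.09 and outside with the GC and length trend removed), NOD signalling partners (0.13), sensor adaptors (0.00206), interferon receptors (0.21) and housekeeping genes (0.17), while epithelial identity genes (-0.14) lay outside, but not with the GC and length trend removed (-0.04).

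In what follows, the tests of depth, goblet share, leukocytes, sex and Nlrp9b sequence, and the Naip5 level, were chosen only after the result was seen. The removal of the GC and length trend was likewise chosen after seeing the data. No biological explanation named by the design was tested because the labels give 1 group. Paneth genes were higher and goblet genes lower in replicate 2. With the GC and length trend removed the medians were 0.83 for Paneth and -0.77 for goblet genes, both outside the central 95%, which argues against that trend as the whole source. Goblet genes of at least 100 FPKM, where depth matters little, had a median of -0.99. A lower share of goblet cells alone stays open, under a rule revised after its values were seen: the differences had an SD of 0.768, above the 0.616 that bounds the central 95% of random lists (0.431 against 0.365 where each list lost its 2 farthest members), but members also made by other cells would move less and widen it, and Muc2 (-1.42), Fcgbp (-1.56), Tff3 (-1.10), Zg16 (-1.05) and Clca1 (-0.99) were all lower, with Ccl9 (1.04) the 1 member of 15 that was higher. Paneth cell share, cell state or handling may contribute and stay open too.

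Interferon-related lists were lower in replicate 2. The median of interferon-stimulated genes was -0.54 with the GC and length trend removed, outside the central 95%, and those of nucleic acid sensors, MHC class I and MHC class II genes were -0.64, -0.20 and -0.53, also outside, so this trend does not account for the whole pattern. Leukocytes left in the sort, which took CD45-negative cells, stay open as a source. Their 46 markers had a median of 0.147 FPKM in replicate 1, against 12.9 FPKM for interferon-stimulated genes. A median over markers of several cell types would stay low with 1 type present, so it cannot decide. The most abundant besides Xbp1, Ccl5, had 12.9 and 5.69 FPKM. At a mean of at least 1 FPKM, 2 lymphocyte markers were higher and 1 lower in replicate 2, and 1 myeloid marker was higher and 2 lower. The sex of the animal cannot be told apart from any other difference between the libraries, since Xist reached 1 FPKM in 1 of 2 libraries. Exposure of the animals to microbes or viruses was not tested.

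Levels of NLRs with near-identical copies could hold reads of those copies. For Nlrp9b, 7.79% of its 50-base words occur in other genes and Nlrp9a and Nlrp9c reached at most 0.348% of its FPKM, which argues against shared reads as the source of its level. For the NAIPs the median was 26.5%, as shared reads would need, so the division of signal among Naip1, Naip2, Naip5 and Naip6 stays open. Words shared with Naip5, at the level of Naip5 and with even coverage assumed, would give at most 56.8% of the level listed for Naip6 in replicate 1, a value that excludes nothing because the coverage is assumed. Naip7 could not be examined in this way.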
